A study of Rattus norvegicus with 12 samples.

How the data were processed

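The deposited table held 36685 rows and 12 arrays of log2 signals. Per the labels, total RNA from rat kidney stored in RNAlater was extracted with Trizol, and 200 ng was amplified and labelled with biotin. The submitters' processing notes name RMA, a method that corrects background, normalizes arrays and combines the probes of a row into 1 log2 value. The version of RMA and the dose and time of the inhibitor are not given in the sources used here. Values ran from 1.48 to 13.4, which fits the log2 unit given by the authors, and were used as deposited. The sample titles give 12 animal codes and the group and day of each array. A description label names a zero-hour biopsy on arrays whose titles give day 2 or day 7, and groups were taken from the titles. No array was excluded.

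The annotation lists 19086 rows: 18511 with 1 gene symbol and 575 with several, and 17599 rows are not listed. Of the single symbols 18394 matched the RefSeq gene names and 117 did not, and 0 were updated. Rows with 1 symbol and values on every array gave 18166 genes, among them 363 microRNA genes. For the 291 genes with more than 1 row the one with the highest mean over all arrays was tested. The 190 control rows had no values on the day 2 arrays, and the distributions of both days differ, so each day was taken to have been normalized apart, which the labels do not state and no test settles. A comparison of treatments is made within a day, while day 7 against day 2 would then hold day and normalization run together. Correlations between arrays reached 0.994 and were 0.978 or more within groups, with at most 18 identical values in a pair of arrays.

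Limma 3.58.1 in R 4.3.3 fitted 4 group means per gene, and 6 comparisons were drawn from that fit with eBayes: treatment at day 2, at day 7, its mean over both days, its difference between days, and day 7 against day 2 in placebo and under anti-miR-182. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 in a comparison. Camera in limma with its preset correlation of 0.01 tested 30 gene lists, adjusted over the lists of a comparison. The estimated correlation and fry were alternatives. The estimated correlation called 0 lists in all 6 comparisons, even cell cycle with time, where nearly all members passed singly. Failing to pass it therefore does not argue against a list. Lists were written from general knowledge of kidney biology before the data were examined: tubular injury, proximal tubule, loop of Henle, distal convoluted and connecting tubule, collecting duct, podocyte, endothelium, fibroblast and extracellular matrix, macrophage, neutrophil, lymphocyte, chemokines, interferon response, complement and acute phase, cell cycle, p53, apoptosis, reported miR-182 targets, FOXO targets, Nrf2 antioxidant response, hypoxia, fatty acid oxidation, oxidative phosphorylation, heat shock and unfolded protein, immediate early genes, red blood cell, perirenal fat, urothelium, smooth muscle and adrenal cortex. The list members Ddx58, Fasl, Acsm2a and Hsd3b1 were taken under other symbols through listed synonyms. These symbols were Rig1, Faslg, Acsm2 and Hsd3b2 in that order. A list score is the mean log2 of its genes minus that of all genes, and was tested by exact permutation of arrays within days, two-sided.

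Genes named in the text follow a rule set before the data were examined: the 10 largest rises and 10 largest falls among genes past the threshold, or, where fewer than 5 passed in a treatment comparison, the 10 with the smallest unadjusted p in each direction. Up to 4 members of each list with the smallest unadjusted p and a fixed set of markers (Foxo1, Foxo3, Havcr1, Lcn2, Spp1, Clu, Cdkn1a, Mki67, Ccl2, Cd68, Col1a1, Slc34a1, Umod and Mir182) were added. Uncharacterised loci were skipped. The groups, comparisons, lists, thresholds and alternatives were also fixed before the data were examined. The alternatives were each day fitted alone, eBayes with a trend or the robust option, array weights, leaving out the dimmest 25% or 50% of genes, quantile normalization, centring on the array median, the mean of a gene's rows, every row, the animal number above or below 90 as covariate (all day 2 animals are above 90, so it varies only within day 7), a minimum log2 difference of 1, an adjusted p under 0.1, and each array left out in turn. Leaving out anti-miR-182 day 2 replicate 3 by itself was listed again after its values were seen.

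The steps were tested on simulated data with 200 changed genes among 18166. A log2 difference of 1 was recovered in 86% of cases at day 2, 88% at day 7 and 97.4% for the mean effect, and a difference of 0.5 in 27.6%, 30.2% and 63.6%. False calls made up 5.15%, 4.49% and 4.96% of calls. Genes were simulated as independent, with 1 spread per gene shared by all groups, and the 200 changed genes ease the adjusted threshold. In the real arrays the median SD of a gene ran from 0.112 (placebo at day 2) to 0.179 (anti-miR-182 at day 2). The rates therefore do not tell which changes are excluded where 0 genes passed. A list shift of 0.3 was called in 20 of 20 runs, with independent genes. In the real arrays, camera with its preset correlation called a median of 8 lists under regroupings of the day 2 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The seed-site test could not be run because no transcript sequences were given.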

Results

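RNA was measured in rat kidneys taken at day 2 and day 7 after ischemia-reperfusion injury, in which the blood supply of the kidney is interrupted and then restored. The rats had been given an inhibitor of the microRNA miR-182 (anti-miR-182) or a placebo. The 12 arrays fall into 4 groups of 3, and every array came from a different animal. Deposited log2 signals had medians between 5.98 and 6.10 on the day 2 arrays and between 5.85 and 5.94 on the day 7 arrays. The number of arrays limits the precision of all comparisons. The first principal component held 51.9% of the variance and separated the days. On the second (10.2%), replicate 3 of the anti-miR-182 group at day 2 lay at -29.41, apart from the other arrays, which lay between -9.18 and 15.4. The spread between animals was larger in that group (median SD of a gene 0.179) than in placebo at day 2 (0.112), placebo at day 7 (0.146) and anti-miR-182 at day 7 (0.137).

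The row of the miR-182 gene itself, Mir182, was higher in kidneys given the inhibitor. At day 2 its log2 signal was 6.40 ± 0.18 under anti-miR-182 and 4.67 ± 0.18 under placebo (SD, n = 3 each), and at day 7 it was 5.52 ± 0.55 and 4.34 ± 0.39. All 6 animals given anti-miR-182 (4.93 to 6.57) lay above all 6 placebo animals (3.97 to 4.84). The mean difference over both days was 1.45 ± 0.17 (SE), which passed over all genes in limma (adjusted p = 0.0104). Within a day the differences were 1.73 ± 0.24 (adjusted p = 0.0771 in limma) and 1.18 ± 0.24 (0.999). Mir183 and Mir96, which lie in the same cluster of microRNA genes, differed by 0.12 ± 0.077 and -0.14 ± 0.13 over both days and did not pass. The placebo levels of Mir182 (4.51), Mir96 (4.67) and Mir183 (3.55) lay below the lower quartile of all genes, 5.47. The call of the mean difference ended in limma without replicate 3 of anti-miR-182 at day 2 (adjusted p = 0.0706), replicate 2 (0.0597) or replicate 3 (0.055) of placebo at day 2, or replicate 1 of anti-miR-182 at day 7 (0.0606), and over 20 settings it ranged from 0.000664 to 0.0706, with log2 differences of 1.33 to 1.60. These settings are those in which the same gene row was tested; 0 genes passed when every row of the table was tested, and leaving out the dimmest 25% or 50% of genes removes Mir182. The array was made for whole transcripts, and the labels do not say which form of the microRNA the row detects.

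**Figure D1:**
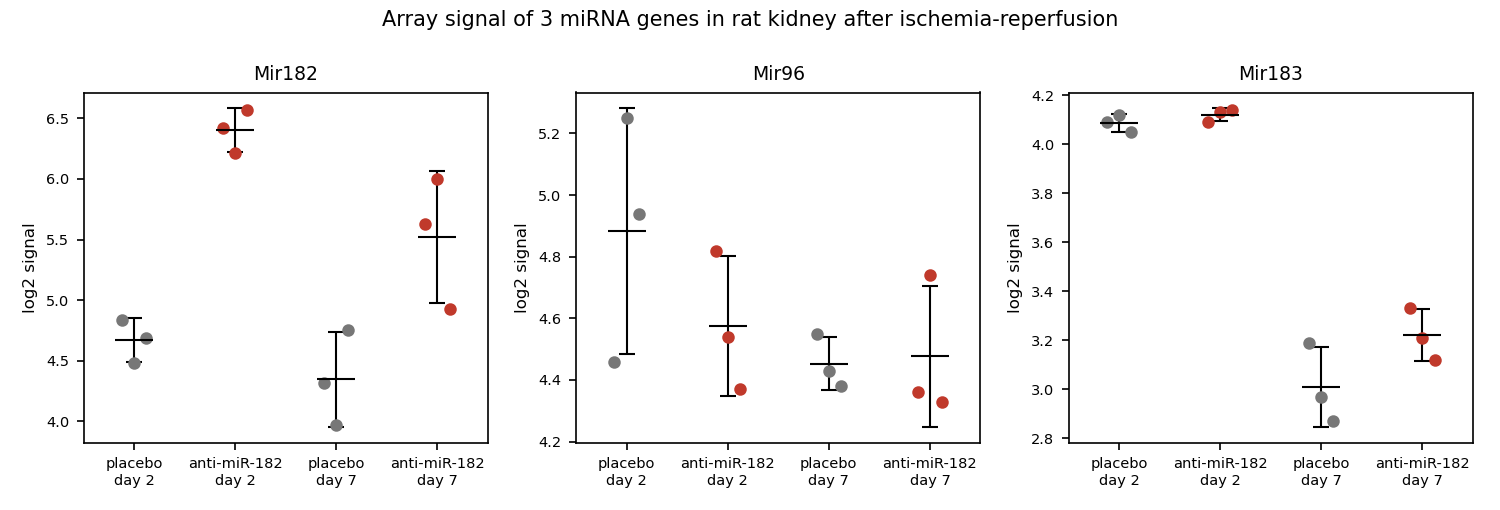
Log2 signal of Mir182, Mir96 and Mir183 on each of the 12 arrays, by group, with the mean and SD of each group of 3. The Mir182 values of the anti-miR-182 arrays (4.93 to 6.57) lie above those of the placebo arrays (3.97 to 4.84), while the groups overlap for Mir96.

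The first comparison asked how kidneys given anti-miR-182 differed from placebo kidneys at day 2 after injury. Genes that injured tubules switch on lay lower under the inhibitor. Of the 28 genes of the tubular injury list, 20 were lower and 8 higher, with a median log2 difference of -0.35. The fibrinogen chains Fga (-0.82 ± 0.23, SE, n = 3 per group), Fgb (-0.93 ± 0.30) and Fgg (-1.10 ± 0.35), the calcium-binding proteins S100a6 (-0.80 ± 0.23) and Anxa2 (-0.72 ± 0.16) and the hyaluronan receptor Cd44 (-0.70 ± 0.22) passed when adjusted over the list alone, and 0 of the 28 passed over all genes. The injury markers Havcr1, which encodes kidney injury molecule 1 (-0.74 ± 0.33), and Lcn2, a lipocalin shed into urine (-1.25 ± 0.55), did not pass, nor did Spp1 (-0.365) or Clu (-0.695 ± 0.398). The list passed with camera in limma (adjusted p = 2.71e-08), but adjusted p = 0.522 with an estimated correlation. Replicate 3 of the anti-miR-182 group carried much of the median difference: its Lcn2 signal was 7.33 against 9.90 and 9.95 in the other animals of its group, and without it the list's median was -0.064 (adjusted p = 0.00279 with camera). The mean scores of the other animals given anti-miR-182 (2.081 and 2.127) still lay below those of the placebo animals (2.27 to 2.39).

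Of 34 cell cycle genes, 31 were lower under anti-miR-182 at day 2, with a median of -0.23. Examples are the mitotic kinases Aurkb (-0.67 ± 0.19) and Ttk (-0.48 ± 0.21) and cyclin A2, Ccna2 (-0.39 ± 0.14), while the proliferation marker Mki67 differed by -0.22 ± 0.21. Of 24 heat shock and unfolded protein genes 20 were lower, with a median of -0.085, among them the asparagine synthetase gene Asns (-0.47 ± 0.18). Of 22 Nrf2 antioxidant genes 17 were lower, with a median of -0.13. Among these the glutathione transferase Gstp1 (-0.90 ± 0.20) passed when adjusted over the list alone, and the heme oxygenase Hmox1 went the other way (0.505 ± 0.154). With camera in limma these lists had adjusted p = 2.71e-08, 0.00203 and 0.00285, and adjusted p = 0.658, 0.522 and 0.522 with an estimated correlation. The cell cycle median was -0.078 without replicate 3 and -0.40 without replicate 2 of the anti-miR-182 group. Without replicate 1 of that group the heat shock and Nrf2 medians were -0.027 and -0.064, and without placebo replicate 1 the heat shock median was -0.15. With the dimmest 50% of genes left out, the heat shock and Nrf2 calls ended (adjusted p = 0.053 and 0.134 with camera), with medians of -0.085 and -0.12.

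Markers of the distal nephron lay higher under anti-miR-182 at day 2. Of 11 distal convoluted and connecting tubule genes 10 were higher, with a median of 0.29, among them the calcium buffer Pvalb (0.34 ± 0.11), the sodium-calcium exchanger Slc8a1 (0.55 ± 0.25) and the kallikrein Klk1 (0.76 ± 0.38). Of 17 collecting duct genes 13 were higher (median 0.20), including the proton pump subunit Atp6v0d2 (0.43 ± 0.14) and the anion exchanger Slc26a4 (0.525 ± 0.221). Of 19 lymphocyte genes 15 were higher (median 0.11), such as the T cell gene Cd8b (0.42 ± 0.13) and the B cell gene Ms4a1 (0.40 ± 0.14). Of 20 immediate early genes 15 were lower (median -0.093), with Myc at -0.42 ± 0.19 and Egr1 at -0.54 ± 0.34, and of 24 apoptosis genes 13 were lower (median -0.036), with the necroptosis kinase Ripk3 at -0.68 ± 0.20 and the TNF receptor Tnfrsf1a at -0.59 ± 0.23. Adjusted p-values with camera in limma were 0.00285, 0.0475, 0.0486, 0.0199 and 0.0266 in that order, and adjusted p = 0.522, 0.734, 0.734, 0.734 and 0.551 with an estimated correlation.

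Each of these 5 calls ended when a single array was left out. Without replicate 1 of anti-miR-182 at day 2, whose collecting duct score of 1.69 stood above those of the others in its group (1.24 to 1.27), camera in limma gave adjusted p = 0.117 for the distal convoluted and connecting tubule list (median 0.19), 0.901 for collecting duct (0.072) and 0.363 for lymphocyte (0.079), and the immediate early and apoptosis medians were -0.15 and -0.077. Without replicate 2 of that group these were -0.14 and -0.066. Without replicate 3 the apoptosis median turned to 0.030 (adjusted p = 0.218), the immediate early median was -0.0064 (0.482), lymphocyte had 0.0526 and the collecting duct median was 0.32. Collecting duct was lost without placebo replicate 1 (0.128) and replicate 3 (0.0986), lymphocyte without placebo replicate 2 (0.109) and replicate 3 (0.0986), and apoptosis (0.112) and immediate early genes (0.129, median -0.052) without placebo replicate 3. The apoptosis median was -0.0595 and -0.0615 without placebo replicates 1 and 2. Collecting duct and lymphocyte were also lost without replicate 1 (0.0548 each) or replicate 2 (0.0545 each) of anti-miR-182 at day 7, which enter only through the shared spread. Quantile normalization ended the lymphocyte and apoptosis calls (0.102 each), array weights ended all 5 (0.0632 to 0.188), and leaving out the dimmest 50% of genes ended lymphocyte (0.27), apoptosis (0.157) and immediate early genes (0.053). In the genes then left the medians of these lists were 0.091, -0.072 and -0.20.

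Single genes did not pass at day 2: limma called 0 of 18166 genes, with 1201 at an unadjusted p under 0.05 (763 higher, 438 lower), where chance alone gives 908. That excess depended on single arrays. The count was 688 and 860 without placebo replicates 3 and 2 of day 2, and 1734 without replicate 1 of anti-miR-182 at day 2. The smallest unadjusted p-values among higher genes belonged to the keratin-associated gene Krtap13-2 (0.73 ± 0.12), the matrix protein dermatopontin, Dpt (0.64 ± 0.12), the angiopoietin receptor Tek (0.79 ± 0.15), Fam180a (0.60 ± 0.13), Depp1 (0.81 ± 0.18) and the sodium-proton exchanger Slc9a4 (0.48 ± 0.11). Among lower genes they belonged to the ribosome assembly factor Rrs1 (-0.79 ± 0.14), the Wnt receptor Ryk (-0.57 ± 0.11), the transcription factor Tead1 (-0.745 ± 0.151), the apoptosis gene Pawr (-0.78 ± 0.16) and Ddias (-0.60 ± 0.13). Umod, the thick limb glycoprotein (0.37 ± 0.15), Egf (1.02 ± 0.34), the chemokine Ccl2 (-0.43 ± 0.25), Cd68 (-0.32), Col1a1 (0.07), Slc34a1 (-0.15) and Cdkn1a (0.01) did not pass either. With 3 animals per group the exact two-sided permutation test of a list score cannot give a p below 0.1. By that test 7 of 30 lists reached it where chance gives 3. They were tubular injury, distal convoluted and connecting tubule, apoptosis, Nrf2, heat shock, hypoxia and adrenal cortex. Camera called neither hypoxia nor adrenal cortex. Cell cycle and lymphocyte (0.2 each), immediate early genes (0.3) and collecting duct (0.5) did not reach it. All lists use the same arrays, so the excess over 3 is not a test. Limma called 1 gene, Mir182, with array weights, the animal number (above or below 90) as covariate, each day fitted alone, or without replicate 2 or 3 of anti-miR-182 at day 7.

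**Figure D2:**
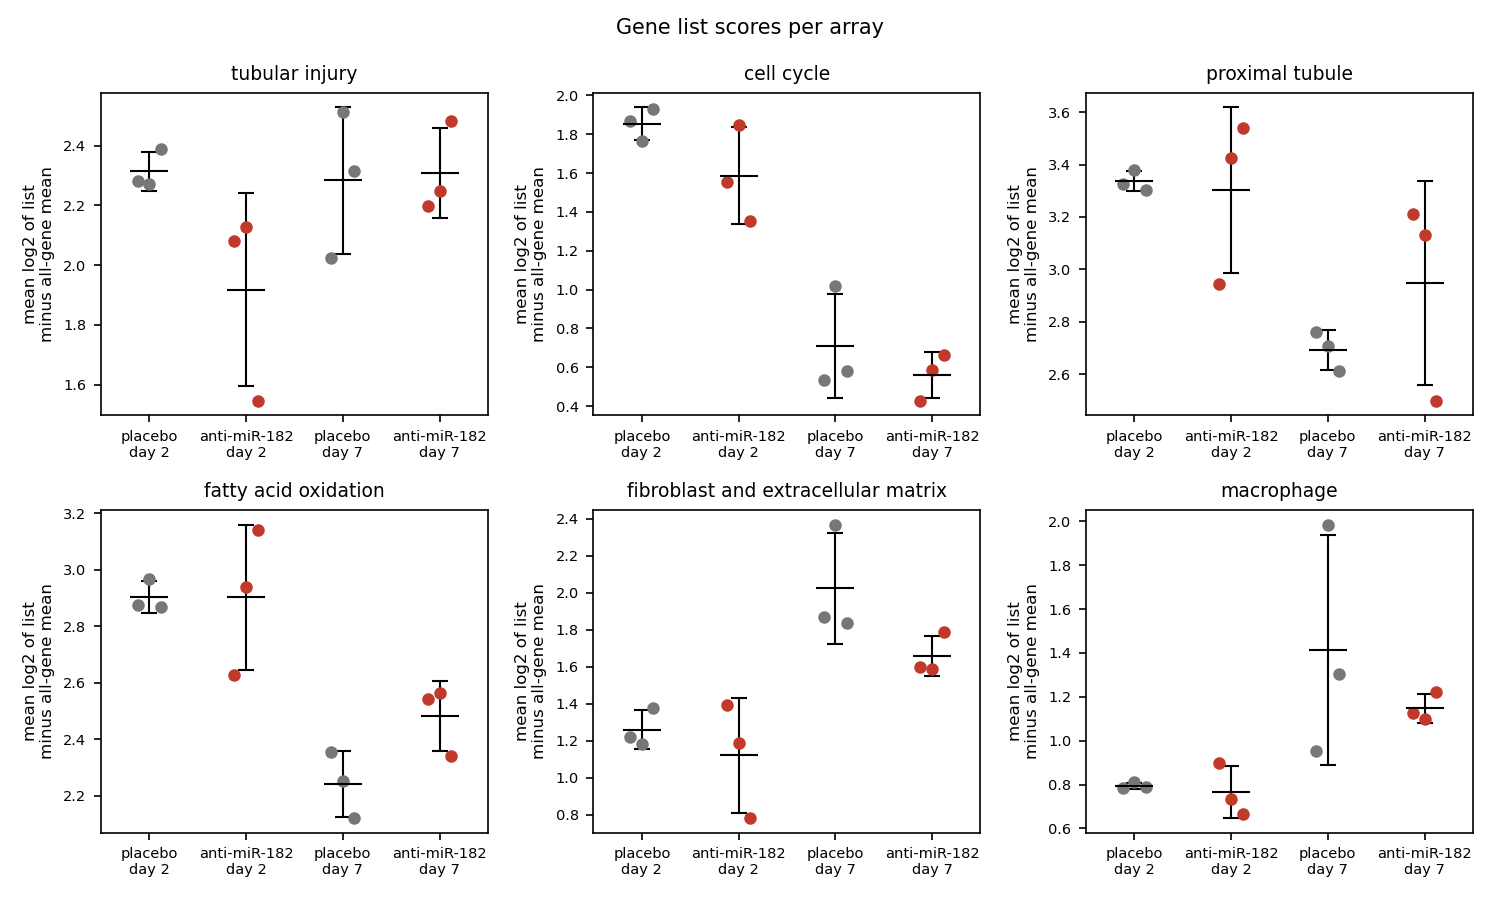
Score of 6 gene lists on each array (mean log2 signal of the list's genes minus the mean of all genes), by group, with the mean and SD of each group of 3. At day 2 the tubular injury score of anti-miR-182 replicate 3 is 1.547, below the other arrays of that day, and at day 7 the macrophage score of placebo replicate 2 is 1.985.

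The same comparison at day 7 asked how the kidneys differed later after injury. Matrix genes lay lower under anti-miR-182: all 23 measured genes of the fibroblast and extracellular matrix list were lower, with a median log2 difference of -0.23. They include the collagens Col1a1 (-0.60 ± 0.18, SE, n = 3 per group) and Col6a3 (-0.53 ± 0.19), the microfibril gene Fbn1 (-0.55 ± 0.19) and periostin, Postn (-1.63 ± 0.55). Of 22 macrophage genes 19 were lower (median -0.28), such as the scavenger receptors Mrc1 (-0.725 ± 0.283) and Cd163 (-0.80 ± 0.42) and Gpnmb (-0.67 ± 0.32). Of 25 interferon response genes 22 were lower (median -0.14), with the antiviral synthetase Oas1a (-0.53 ± 0.14) past the threshold when adjusted over the list alone. Camera in limma gave adjusted p = 1.1e-10, 4.66e-05 and 8.08e-06, and adjusted p = 0.451, 0.744 and 0.446 with an estimated correlation. Placebo replicate 2 had the highest macrophage score (1.985 against 0.951 and 1.302 in its group, and 1.10 to 1.22 under anti-miR-182). Without it the macrophage median turned to 0.016 (adjusted p = 0.772 with camera), the matrix median was -0.13 (0.000962) and the interferon median -0.089 (0.00744). Without placebo replicate 1 the macrophage median was -0.48, and without placebo replicate 3 the matrix median was -0.42.

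Metabolic genes of the proximal tubule lay higher under anti-miR-182 at day 7. Of 30 proximal tubule genes 27 were higher (median 0.26), such as the gluconeogenic enzymes Pck1 (0.64 ± 0.29) and Fbp1 (0.59 ± 0.25), the inositol oxygenase Miox (0.39 ± 0.18) and the transporter Slc7a13 (0.55 ± 0.26). Of 27 fatty acid oxidation genes 23 were higher (median 0.21), including the fatty acid hydroxylase Cyp4a1 (0.77 ± 0.27), the peroxisomal enzyme Ehhadh (0.57 ± 0.22) and the enoyl-CoA isomerase Eci1 (0.49 ± 0.19). None of these genes passed over all genes. Camera in limma gave adjusted p = 1e-06 and 6.74e-08 for the lists, and adjusted p = 0.524 and 0.451 with an estimated correlation. Replicate 3 of the anti-miR-182 group had a proximal tubule score of 2.499, against 3.13 and 3.21 in its group and 2.61 to 2.76 under placebo. Without that animal the proximal tubule median was 0.45, and without replicate 1 of its group it was 0.12 (adjusted p = 0.0249 with camera). Without placebo replicate 3 the fatty acid oxidation median was 0.13 (0.00223).

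A further 5 lists passed with camera in limma at day 7. Cell cycle genes were lower in 30 of 34 cases (median -0.12), with Ccna2 at -0.47 ± 0.14 and Mki67 at -0.26 ± 0.21. Urothelium genes were lower in 8 of 10 cases (median -0.25), with the uroplakin Upk1b at -1.03 ± 0.42 and the keratin Krt14 at -0.46 ± 0.15. Complement and acute phase genes were lower in 9 of 12 cases (median -0.10), with the protease inhibitor A2m (-0.91 ± 0.26) past the threshold when adjusted over the list alone. Collecting duct genes were lower in 13 of 17 cases (median -0.084), including the water channel Aqp4 (-0.865 ± 0.311), and heat shock and unfolded protein genes were higher in 17 of 24 (median 0.073). Adjusted p-values were 0.000136, 0.00194, 0.00512, 0.0136 and 0.0407 in that order, and adjusted p = 0.77, 0.446, 0.446, 0.744 and 0.744 with an estimated correlation.

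All of these 5 calls depended on single arrays. Without placebo replicate 2 camera in limma gave adjusted p = 0.993 for cell cycle (median 0.0050) and 0.176 for complement (-0.071), and the collecting duct and heat shock medians were -0.16 and 0.11. Without placebo replicate 1 urothelium had 0.21 (median -0.13), collecting duct 0.798 (-0.027) and heat shock 0.161, while the cell cycle and complement medians were -0.25 and -0.20. Without placebo replicate 3 heat shock had 0.379 (0.042), and the urothelium and collecting duct medians were -0.38 and -0.16. Without replicate 1 of anti-miR-182 cell cycle had 0.0583 (median -0.059), complement 0.0536 (-0.055) and heat shock 0.24, and the collecting duct median was -0.13. Without replicate 3 collecting duct had 0.107 (-0.019) and heat shock 0.0597.

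At day 7 limma again called 0 of 18166 genes, with 593 at an unadjusted p under 0.05 (292 higher, 301 lower), where chance alone gives 908, and a smallest adjusted p of 0.999. The smallest unadjusted p-values among higher genes belonged to the olfactory receptor gene Or52e18 (0.77 ± 0.16), the transcription factor Gsc (0.60 ± 0.13), the fatty acid ester hydrolase Adtrp (0.96 ± 0.21) and the trefoil factor Tff3 (0.85 ± 0.19). Among lower genes they belonged to Slc9a4 (-0.52 ± 0.11), the Wnt antagonist Sfrp4 (-0.95 ± 0.20), the cytoskeletal actin Actb (-0.51 ± 0.12), the growth factor Igf1 (-0.965 ± 0.227) and the keratin Krt15 (-1.25 ± 0.31). Havcr1 (0.43 ± 0.33), Lcn2 (0.44 ± 0.55), Spp1 (-0.07), Ccl2 (-0.02), Cd68 (-0.42 ± 0.30) and Umod (0.01) did not pass. Krt15 signals were 7.03 and 6.95 in placebo replicates 1 and 2, 5.38 in replicate 3 and 5.04 to 5.30 under anti-miR-182. Without placebo replicate 3 limma called Krt15 (-1.78), Upk1b (-1.76) and the urea transporter Slc14a2 (-1.17), and without placebo replicate 1 it called C3h15orf48 (-1.14). The exact two-sided permutation test of list scores, with a smallest possible p of 0.1, reached it for 1 of 30 lists, the matrix list, where chance gives 3.

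**Figure D3:**
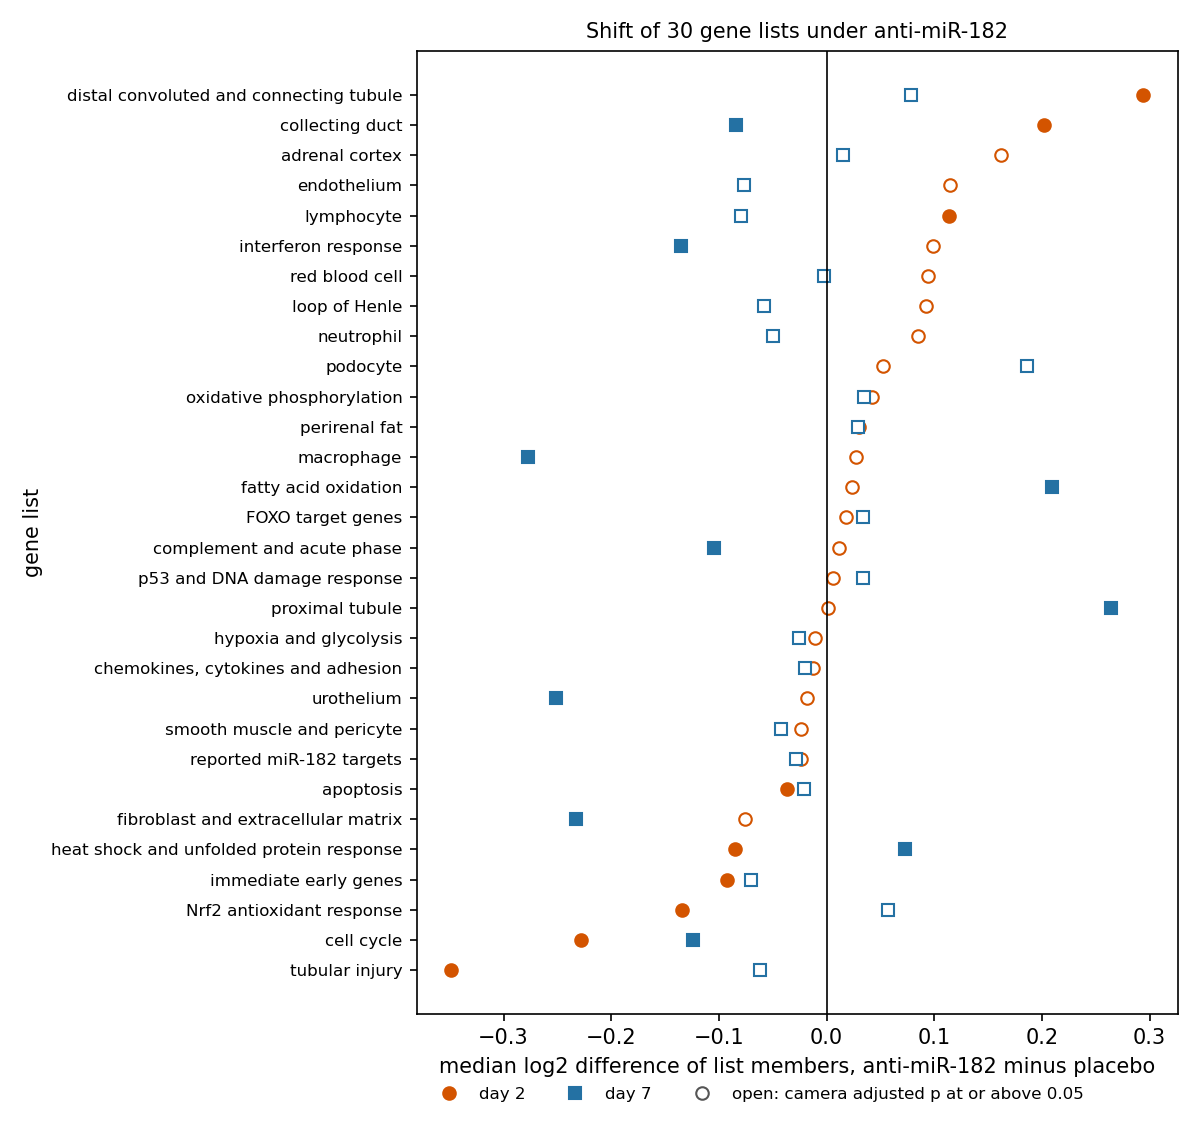
Median log2 difference, anti-miR-182 minus placebo, of 30 gene lists at day 2 (circles) and day 7 (squares); open symbols mark lists with a camera adjusted p of 0.05 or more. The tubular injury list lies at -0.35 at day 2 and -0.062 at day 7, and the proximal tubule list at 0.0010 and 0.26.

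Over both days together, genes of cell division, matrix and tubular injury lay lower under anti-miR-182 and distal tubule genes lay higher. The medians of the mean effect were -0.20 for cell cycle (32 of 34 genes lower), -0.20 for matrix (22 of 23 lower), -0.18 for tubular injury (22 of 28 lower) and 0.20 for the distal convoluted and connecting tubule (11 of 11 higher). Ccna2 (-0.43 ± 0.099), Anxa2 (-0.51 ± 0.11) and S100a6 (-0.71 ± 0.16) passed when adjusted over their lists alone, as did Krt14 (-0.43 ± 0.10) and Ms4a1 (0.37 ± 0.10) in theirs. With camera in limma these 4 lists had adjusted p = 9.66e-11, 2.98e-08, 2.94e-05 and 0.000925, and adjusted p = 0.57 each with an estimated correlation. They passed with camera without each of the 12 arrays in turn. Exact permutation of their scores per array gave p = 0.095, 0.065, 0.215 and 0.08 (two-sided, smallest possible p 0.005). By that test 0 of 30 lists had p under 0.05 for the mean effect. Without replicate 3 of anti-miR-182 at day 2 the cell cycle, matrix and tubular injury medians were -0.11, -0.11 and -0.044. Without placebo replicate 2 at day 7 the cell cycle, tubular injury and distal tubule medians were -0.10, -0.095 and 0.13, and without replicate 1 of anti-miR-182 at day 7 the distal tubule median was 0.12. In limma 957 genes had an unadjusted p under 0.05, where chance alone gives 908. Leave-outs gave 669 (without placebo replicate 3 at day 2) to 1668 (without replicate 1 of anti-miR-182 at day 2). Over all genes 1 gene, Mir182, passed. Among the others the smallest p-values belonged to the ribosomal protein Mrpl1 (0.53 ± 0.12), Rrs1 (-0.48 ± 0.095), the secretory pathway gene Ssr1 (-0.47 ± 0.094), Pawr (-0.55 ± 0.11) and the Brca1 partner Bard1 (-0.42 ± 0.091), none of which passed (adjusted p = 0.741).

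The genes on which miR-182 is reported to act did not move together. Of 28 measured reported targets 12 were higher and 16 lower at each day, with medians of -0.024 at day 2, -0.028 at day 7 and -0.034 for the mean effect, and camera in limma gave adjusted p = 0.143, 0.529 and 0.111. The transcription factor Foxo1 differed by -0.13 ± 0.12 at day 2 and 0.24 ± 0.12 at day 7, and Foxo3 by -0.06 ± 0.13 and -0.04 (SE, n = 3 per group). Other members were Brca1 (-0.49 ± 0.17) and Igf1r (-0.35) at day 2 and the translation inhibitor Pdcd4 (-0.39 ± 0.14) at day 7. None passed, over all genes or over the list alone. The list's mean per array differed by -0.047 over both days (exact permutation p = 0.16, two-sided). Of 27 FOXO target genes 16 were higher at day 2 and 15 at day 7, with medians of 0.018 and 0.034 (camera in limma, adjusted p = 0.443 and 0.636), and their mean at day 2 was lower, at -0.028. Among them the pyruvate dehydrogenase kinase Pdk4 (-0.73 ± 0.27) and Cited2 (-0.35 ± 0.11) had the smallest p-values at day 2.

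A further 5 lists, fatty acid oxidation, macrophage, proximal tubule, apoptosis and immediate early genes, passed for the mean effect with camera in limma (adjusted p = 0.00174, 0.00793, 0.016, 0.0183 and 0.022). With an estimated correlation they had adjusted p = 0.638, 0.668, 0.662, 0.57 and 0.662, and each call also ended in some leave-outs. Fatty acid oxidation (median 0.12) was lost without replicate 3 of anti-miR-182 at day 2 (0.211) or placebo replicate 3 at day 7 (0.0688), and its median was 0.19 without replicate 1 of anti-miR-182 at day 2. Macrophage (-0.0997) was lost without replicate 2 of anti-miR-182 at day 2 (0.0612), and without placebo replicate 2 at day 7 its median was 0.00092 (0.978). That median was -0.16 without replicate 1 of anti-miR-182 at day 2 and -0.21 without placebo replicate 1 at day 7. Proximal tubule (0.11) was lost without replicate 2 or 3 of anti-miR-182 at day 2, replicate 1 or 2 of anti-miR-182 at day 7, or placebo replicate 3 at day 7, with adjusted p up to 0.381 and medians from 0.043 to 0.24, the highest without replicate 3 of anti-miR-182 at day 7; it was 0.19 without replicate 1 of anti-miR-182 at day 2. Apoptosis (-0.055) was lost without replicate 3 of anti-miR-182 at day 2, replicate 2 of anti-miR-182 at day 7 or placebo replicate 3 at day 2, with adjusted p up to 0.106, and its median was -0.034 without placebo replicate 1 at day 2. Immediate early genes (-0.061) were lost without replicate 3 of anti-miR-182 at day 2, replicate 1 of anti-miR-182 at day 7, or replicate 3 of placebo at either day, with adjusted p up to 0.434, and had medians of -0.095 without replicate 1 of anti-miR-182 at day 2 and -0.096 without placebo replicate 1 at day 7.

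The difference between the effects at both days was tested as the treatment effect at day 7 minus that at day 2. All 24 heat shock and unfolded protein genes had a higher effect at day 7 (median 0.16), and 22 of 25 interferon genes had a lower one (median -0.36). Within the interferon list Oas1a (-0.79 ± 0.19, SE) passed when adjusted over the list alone, as did the fibrinogen genes Fga (1.65 ± 0.32), Fgb (1.80 ± 0.43) and Fgg (1.68 ± 0.49) in the tubular injury list and Tek (-0.91 ± 0.22) in the endothelium list. Both the heat shock and the interferon list had adjusted p = 8.45e-05 with camera in limma, and adjusted p = 0.415 with an estimated correlation, and both passed without each array in turn. Over all genes limma called 0, with 713 at an unadjusted p under 0.05 where chance alone gives 908, and the smallest adjusted p was 0.284 for Slc9a4 (-1.001 ± 0.156). In leave-outs the count of 713 ran from 549 (without placebo replicate 3 at day 2) to 1085 (without replicate 3 of anti-miR-182 at day 2). Across 18166 genes the effects at both days correlated with r = 0.102 and rho = 0.092, and 53% of genes had the same sign. Genes are not independent replicates, and 400 relabellings of arrays within days gave exact p = 0.43 and 0.46 (two-sided).

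Between day 2 and day 7 in placebo kidneys 32 of 34 cell cycle genes, 22 of 27 fatty acid oxidation genes and 17 of 30 proximal tubule genes were called lower, while 10 of 23 matrix genes and 7 of 22 macrophage genes were called higher and 3 macrophage genes lower. The lists of these genes passed with camera in limma, and had adjusted p = 0.369 to 0.472 with an estimated correlation. That setting did not call cell cycle either, where 32 of 34 genes were called singly. Failing to pass it therefore does not argue against a list. Cyclin B1, Ccnb1, fell by 2.32 ± 0.19 on the log2 scale (SE, n = 3 per group, adjusted p = 3.59e-05 in limma), Mki67 by 1.73 ± 0.21, the gluconeogenic enzyme Pck1 by 2.50 ± 0.29 and the fatty acid oxidation enzyme Ehhadh by 2.29 ± 0.22. The pantetheinase Vnn1 (-2.47 ± 0.28), the glucuronosyltransferase Ugt2b7 (-2.68 ± 0.51), the organic anion transporter Slc22a6 (-1.65 ± 0.29), the antioxidant enzymes Txnrd1 (-1.24 ± 0.11) and Gstp1 (-1.40 ± 0.20) and Fbp1 (-1.46) also fell. The protease inhibitor A2m rose by 2.91 ± 0.26 (adjusted p = 5.25e-05 in limma), Postn by 2.98 ± 0.55, Fbn1 by 1.01 ± 0.19 and the fibroblast and T cell antigen Thy1 by 0.70 ± 0.12. The macrophage genes Mrc1 (1.84 ± 0.28) and Adgre1 (1.39 ± 0.21), the lectin receptor Clec4e (1.75 ± 0.26), the MHC class II gene RT1-Da (1.80 ± 0.27), the T cell genes Cd2 (1.18 ± 0.24) and Cd4 (1.08 ± 0.23) and the interferon genes Isg15 (1.03 ± 0.18) and Usp18 (1.25 ± 0.27) rose as well. These genes kept their call under quantile normalization and centring. Not all genes chosen by the rule did: of 116 called in placebo, quantile normalization ended 39 calls and centring 14. The proximal tubule marker Slc34a1 fell by 0.745, a call that ended without placebo replicate 1 of day 2 or replicate 3 of day 7.

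Limma called 5080 of 18166 genes in placebo, 766 higher and 4314 lower at day 7, around an all-gene median of -0.18. The arrays of both days appear to have been normalized apart, which was inferred and not tested, and day and normalization run then cannot be told apart. With quantile normalization of all 12 arrays 1419 rose and 1471 fell, with a median of -0.0096, and with each array centred on its median 1195 rose and 2272 fell. Relative to the all-gene median the cell cycle list shifted by -1.29 (32 of 34 genes fell), matrix by 0.65 (10 of 23 rose), macrophage by 0.61 (7 of 22 rose, 3 fell), complement by 0.53 (3 of 12 rose), interferon by 0.47 (9 of 25 rose, 1 fell), lymphocyte by 0.29 (6 of 19 rose, 2 fell), fatty acid oxidation by -0.50 (22 of 27 fell) and proximal tubule by -0.53 (17 of 30 fell). Adjusted p-values with camera in limma ran from 2.63e-18 for cell cycle to 0.00108 for lymphocyte, and with an estimated correlation adjusted p = 0.369, 0.369, 0.462, 0.235, 0.235, 0.427, 0.401 and 0.472 in the order given. Without placebo replicate 2 at day 7 the macrophage and complement shifts were 0.385 and 0.34, and without placebo replicate 3 at day 2 the lymphocyte shift was 0.15. The lymphocyte call ended when the dimmest 50% of genes were left out (adjusted p = 0.183). Nrf2 (-0.32), oxidative phosphorylation (-0.20) and heat shock genes (-0.18) passed with adjusted p = 0.0181, 0.0131 and 0.0317, and adjusted p = 0.401, 0.709 and 0.462 with an estimated correlation. The last 2 did not pass under quantile normalization (0.309 and 0.296). With the dimmest 50% of genes left out the 3 calls ended (0.0688, 0.126 and 0.126), and with the animal number above or below 90 as covariate oxidative phosphorylation did not pass (0.0853). Without placebo replicate 3 at day 7 Nrf2 had 0.0682, oxidative phosphorylation 0.279 and heat shock 0.0933, without placebo replicate 2 at day 2 oxidative phosphorylation had 0.06 and heat shock 0.0791, and without placebo replicate 1 at day 7 heat shock had 0.0755. The number of genes called was 3198, 3212 and 3306 without placebo replicates 1, 2 and 3 at day 2.

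The same change with time was tested under anti-miR-182. Cell cycle genes fell again, with Ccnb1 at -2.22 ± 0.19 (SE, n = 3 per group, adjusted p = 4.65e-05 in limma), the mitotic kinase Cdk1 at -2.06 ± 0.25 and Mki67 at -1.77 ± 0.21. Tissue kallikreins Klk1c10 (-3.30 ± 0.40) and Klk1 (-2.004 ± 0.384), Pck1 (-2.03 ± 0.29), Ehhadh (-1.565 ± 0.218), the retinol carrier Rbp4 (-2.08 ± 0.39), Egf (-1.46 ± 0.34), the intercalated cell genes Atp6v0d2 (-1.09 ± 0.14) and Slc26a4 (-1.17 ± 0.22) and the stress genes Hmox1 (-0.72) and Mt1 (-0.94) fell. A2m (2.19 ± 0.26), the cytokines Il19 (2.15 ± 0.36) and Il24 (2.09 ± 0.49), complement C3 (1.74 ± 0.45), Clec4e (1.74 ± 0.26), Fga (1.13 ± 0.23), the fatty acid carrier Fabp4 (1.34) and Cd2 (0.996) rose. These genes kept their call under quantile normalization and centring. Of all 113 called genes chosen by the rule, quantile normalization ended 41 calls and centring 35. Lcn2 rose by 2.004 ± 0.546 (adjusted p = 0.0165 in limma), but by 1.14 without replicate 3 of day 2, and its call ended without replicate 3 of day 7. Mir182 fell by 0.88 ± 0.24 (adjusted p = 0.0163), a call that ended under quantile normalization, under centring and without replicate 3 of day 7. Mir183 fell by 0.895 ± 0.109, and by 1.07 ± 0.11 in placebo.

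Under anti-miR-182 limma called 5002 genes, 487 higher and 4515 lower, around an all-gene median of -0.205, and here too day and the inferred normalization run cannot be told apart. Quantile normalization gave 1261 higher and 1415 lower, and centring 1056 and 1414. The animal number above or below 90 as covariate gave 271 and 3096. Relative to the all-gene median the cell cycle list shifted by -1.095 (32 of 34 genes fell), matrix by 0.52 (4 of 23 rose), macrophage by 0.44 (3 of 22 rose, 3 fell), interferon by 0.30 (2 of 25 fell), tubular injury by 0.28 (4 of 28 rose, 3 fell), complement by 0.15 (4 of 12 rose, 2 fell) and fatty acid oxidation by -0.38 (19 of 27 fell). The unadjusted median of the complement list was -0.052 and its mean 0.36. Camera in limma gave adjusted p = 8.1e-17, 2.55e-08, 0.000174, 0.0017, 0.000174, 0.00759 and 0.000174, and adjusted p = 0.59, 0.59, 0.777, 0.59, 0.777, 0.59 and 0.777 with an estimated correlation. Without replicate 3 of day 2 the matrix, tubular injury and fatty acid oxidation shifts were 0.29, 0.13 and -0.23 and the complement shift was 0.25, without replicate 1 the complement shift was 0.23, and without replicate 2 the interferon shift was 0.16. Collecting duct (-0.39), oxidative phosphorylation (-0.16), perirenal fat (0.24) and chemokine genes (0.11) passed with adjusted p = 0.0354, 0.0228, 0.0228 and 0.0373, and adjusted p = 0.777, 0.835, 0.59 and 0.777 with an estimated correlation. The last 3 did not pass under quantile normalization (0.193, 0.085 and 0.17), nor chemokines under centring (0.12). With the animal number above or below 90 as covariate collecting duct (0.254), oxidative phosphorylation (0.168) and chemokines (0.16) did not pass, nor with array weights (0.0539, 0.086 and 0.0539). With the dimmest 50% of genes left out perirenal fat (0.12) and chemokines (0.741) did not pass. Without replicate 3 of day 2 oxidative phosphorylation had 0.728, perirenal fat 0.131 and chemokines 0.188, without replicate 1 of day 2 collecting duct had 0.21, without replicate 2 of day 7 perirenal fat had 0.053, and without replicate 3 of day 7 collecting duct had 0.0627, oxidative phosphorylation 0.0911 and chemokines 0.0913. Without replicate 1 of day 2 the oxidative phosphorylation and chemokine shifts were -0.30 and 0.25. The number of genes called was 3069 without replicate 2 of day 2, 3221 without replicate 1 of day 7 and 3229 without replicate 3 of day 7.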

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

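For 13 gene lists the treatment effect at day 7 differed from that at day 2 with camera in limma, a difference that was itself tested; the lists were fixed beforehand, while the tests of 1 animal at day 2 and of kidney regions were chosen after the result was seen. The median effect at day 7 minus that at day 2 was higher for tubular injury (0.1553, 20 of 28 genes higher, adjusted p = 9.31e-05), proximal tubule (0.2993, 25 of 30, 0.000249), fatty acid oxidation (0.135, 21 of 27, 0.000258), Nrf2 antioxidant response (0.153, 17 of 22, 0.0019) and heat shock and unfolded protein response (0.1575, 24 of 24, 8.45e-05). It was lower for interferon response (-0.3604, 22 of 25 lower, 8.45e-05), collecting duct (-0.3574, 14 of 17, 0.000333), lymphocyte (-0.2689, 18 of 19, 0.00149), matrix (-0.2195, 18 of 23, 0.00782), macrophage (-0.232, 19 of 22, 0.0214), loop of Henle (-0.3705, 9 of 13, 0.0323), endothelium (-0.1584, 12 of 14, 0.0327) and urothelium (-0.1917, 9 of 10, 0.0387). Adjusted p = 0.415 to 0.711 with an estimated correlation, so none passed that way. By exact permutation of list scores per array 0 of 30 lists passed after adjustment. Of 100 groupings of the arrays, the real one included, 14 gave at least the real 13 lists (highest other 16), so chance is not excluded for their number. For single genes the real count was 0, so that all 100 reach it by construction (highest other 1) and nothing follows from it.

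Heat shock and interferon lists kept their call without each array, with medians of 0.132 to 0.208 and -0.427 to -0.254. Without replicate 1 of anti-miR-182 at day 2, camera in limma ended the calls of collecting duct (-0.19, adjusted p = 0.189), endothelium (-0.060, 0.584), fatty acid oxidation (-0.0063, 0.23), matrix (-0.15, 0.429), loop of Henle (-0.32, 0.189), lymphocyte (-0.23, 0.0513), macrophage (-0.21, 0.23), proximal tubule (0.083, 0.189) and urothelium (-0.14, 0.189), and the tubular injury median was 0.25. Without replicate 3 of that group the tubular injury median was -0.0067 with the call kept (0.0479), the loop call ended (0.0753), and the endothelium, fatty acid oxidation and matrix medians were -0.28, 0.26 and -0.35; without replicate 2 tubular injury was at 0.30. Without replicate 2 of anti-miR-182 at day 7 the calls of endothelium (0.0691), matrix (0.083), loop (0.137), macrophage (0.126) and urothelium (0.144) ended and proximal tubule was at 0.19, without replicate 1 that of endothelium (0.118) ended and tubular injury was at 0.28, and without replicate 3 that of urothelium (0.074) ended and fatty acid oxidation and proximal tubule were at 0.24 and 0.49. Without placebo replicate 2 at day 7 the calls of matrix (-0.086, 0.37), lymphocyte (-0.15, 0.111), macrophage (-0.0087, 0.433) and urothelium (0.126) ended and tubular injury was at 0.28. Without placebo replicate 1 at day 7 those of endothelium (0.123), loop (-0.13, 0.797) and urothelium (-0.098, 0.465) ended, and fatty acid oxidation, lymphocyte, macrophage and Nrf2 were at 0.22, -0.45, -0.44 and 0.24. Without placebo replicate 3 at day 7 that of Nrf2 (0.0565) ended, and fatty acid oxidation, proximal tubule and urothelium were at 0.075, 0.19 and -0.32. At day 2, urothelium was lost without placebo replicate 1 (0.09) and 2 (0.112), endothelium without replicate 2 (0.0519) and loop without replicate 3 (0.114).

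The lower tubular injury list at day 2 was weighed in tests chosen after the result was seen. Without replicate 3 of the anti-miR-182 group the median was -0.0639 instead of -0.35, so the size of the median shift rests largely on 1 animal, in which Lcn2 and Havcr1 were the lowest of that day, while the list's mean scores in the other animals of its group (2.081 and 2.127) still lay below all placebo scores (2.27 to 2.39). Pieces with more medulla were taken to raise the loop of Henle, collecting duct and urothelium lists and to lower the proximal tubule list, each by over 0.1. Their medians were 0.092, 0.20, -0.0186 and 0.0010. By the rule first written, a urothelium median that was not positive or a proximal tubule median that was positive spoke against more medulla, and both occurred. The urothelium and proximal tubule scores differed by less than their spread, however, so more medulla stays open. The bound that takes this spread into account was set after the values were seen. An effect of the inhibitor also stays open and was not tested apart from these.

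At day 7 the lower matrix and macrophage lists and the higher proximal tubule and fatty acid oxidation lists were weighed as 1 pattern; the region test was chosen after the result was seen and the test of single animals before. In 2 of 24 cases of a list and a left-out animal the call ended or the median fell below 50% of its value, so part of the pattern rests on single animals: the macrophage median was 0.016 without placebo replicate 2, and the proximal tubule median 0.12 instead of 0.26 without anti-miR-182 replicate 1. More cortex in the anti-miR-182 pieces would raise podocyte against loop of Henle genes, and that difference was 0.197 (exact permutation p = 0.5, two-sided), which leaves it open. The urothelium and collecting duct lists, taken as signs of medulla at day 2, were not part of that test. Both were lower at day 7 (medians -0.25 and -0.084), the direction that more cortex would give. Urothelium scores were -0.015 and -0.175 in placebo replicates 1 and 2, -0.64 in placebo replicate 3 and -0.617 to -0.472 under anti-miR-182. Both calls ended without placebo replicate 1. An effect of the inhibitor also stays open, and no test separated it from single animals or more cortex.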

How the results depend on the processing

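The cause of the following changes was not tested unless stated. Limma called 1 gene instead of 0 at day 2 with an adjusted p under 0.1, array weights, the animal number (above or below 90) as covariate or each day fitted alone, and 0 to 1 with an array left out (1 without anti-miR-182 day 7 replicate 2 or 3); the gene was Mir182. At day 7 leave-outs gave 0 to 3 (1 without placebo day 7 replicate 1, 3 without replicate 3), and for the interaction 0 to 1 (1 without placebo day 7 replicate 3). For the mean effect the count was 0 instead of 1 with the dimmest 25% or 50% of genes left out, which removes Mir182 by construction, and with every row tested. Leave-outs gave 0 to 4: 0 without anti-miR-182 day 2 replicate 3, placebo day 2 replicate 2 or 3 or anti-miR-182 day 7 replicate 1, 2 without anti-miR-182 day 2 replicate 1, 4 without placebo day 7 replicate 1 and 3 without replicate 3. With time in placebo, 5080 genes became 385 with a minimum log2 of 1, 3364 without the dimmest 50% and 2890 with quantile normalization, and 3198 to 5773 in leave-outs. Under anti-miR-182, 5002 became 308, 2651, 2676 and, with centring, 2470, and 3069 to 5072 in leave-outs. Camera with an estimated correlation called 0 lists in all 6 comparisons. Fry called 0 in the 4 treatment comparisons, 14 with time in placebo (3 up, 11 down) and 12 under anti-miR-182 (0 up, 12 down). Camera with the preset correlation called 5 up and 6 down in placebo and 7 up and 4 down under anti-miR-182. Fry tests a list against no change and not against other genes. Its calls with time therefore also hold the all-gene medians of -0.18 and -0.205. In leave-outs camera called 5 (without placebo day 2 replicate 3) to 10 lists at day 2, 7 to 13 at day 7, 5 (without anti-miR-182 day 2 replicate 3) to 12 for the mean effect, and 4 (without anti-miR-182 day 2 replicate 1; 8 without anti-miR-182 day 7 replicate 2) to 16 for the interaction. Leaving out the dimmest 50% of genes also ended the camera calls of immediate early genes (adjusted p = 0.053), lymphocyte (0.27), apoptosis (0.157), heat shock (0.053) and Nrf2 (0.134) lists at day 2, and of apoptosis (0.12), macrophage (0.12) and immediate early genes (0.082) for the mean effect. The mean-effect medians of these last lists were then -0.055, -0.096 and -0.14, against -0.055, -0.0997 and -0.061 with all genes. Quantile normalization ended apoptosis (0.0623) for the mean effect and urothelium (0.0566) for the interaction, and array weights macrophage (0.0625) and urothelium (0.0817) for the interaction. Among lists that had passed, medians turned sign in 6 cases, given here with the range over leave-outs. Apoptosis at day 2 ran from -0.07689 to 0.03003 (positive without anti-miR-182 day 2 replicate 3), macrophage at day 7 from -0.4774 to 0.01592, cell cycle at day 7 from -0.2482 to 0.005029 and macrophage in the mean effect from -0.213 to 0.000918 (all 3 positive without placebo day 7 replicate 2). In the interaction tubular injury ran from -0.006679 (without anti-miR-182 day 2 replicate 3) to 0.3048 and fatty acid oxidation from -0.006253 (without anti-miR-182 day 2 replicate 1) to 0.2645. Of the called genes named for the change with time, quantile normalization ended 39 of 116 calls in placebo and 41 of 113 under anti-miR-182, and centring 14 and 35. The correlation of effects between days was 0.142 without the dimmest 50% of genes (exact permutation p = 0.45, two-sided). The test of miR-182 seed sites and its alternatives were not run, because no transcript sequences were given. No paired analysis was possible because the groups share no animal numbers.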

Other observations

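Several cell types not described so far had lists that did not pass in a treatment comparison within a day. At day 2 the thick limb genes of the loop of Henle list had a median log2 difference of 0.092 (11 of 13 higher, adjusted p = 0.193 with camera in limma) and endothelium 0.12 (0.103), in which the angiopoietin receptor Tek passed when adjusted over the list alone. At day 7 they were -0.059 (0.164) and -0.077 (0.377). Podocyte genes had medians of 0.053 and 0.19 (0.911 and 0.247), with the chloride channel protein Clic5 at 0.50 ± 0.18 at day 7 (SE, n = 3 per group). Neutrophil genes had 0.085 and -0.050 (0.599 and 0.515), chemokines -0.013 and -0.020 (0.599 and 0.609), smooth muscle genes -0.024 and -0.042 (0.185 and 0.342) and adrenal cortex genes 0.16 and 0.015 (0.0592 and 0.946), with all 8 adrenal genes higher at day 2, among them the aldosterone synthase Cyp11b2 (0.40 ± 0.19).

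Stress and energy lists that did not pass within a day were p53 (0.0062 at day 2 and 0.034 at day 7, adjusted p = 0.599 and 0.91 with camera in limma), hypoxia (-0.010 and -0.025, 0.155 and 0.377), oxidative phosphorylation (0.042 and 0.035, 0.884 and 0.377), red blood cell (0.094 and -0.0024, 0.818 and 0.704) and perirenal fat (0.030 and 0.029, 0.747 and 0.737). The oxygen sensor Egln1 differed by -0.54 ± 0.19 at day 2 and did not pass. At day 2 the median was above 0 and the test pointed down for proximal tubule (median 0.0010, mean -0.0051), macrophage (0.027 and -0.00014), complement (0.011 and -0.059), p53 (0.0062 and -0.019), FOXO targets (0.018 and -0.028) and perirenal fat (0.030 and -0.024), and for podocyte (0.053 and 0.034) and fatty acid oxidation (0.024 and 0.026), whose means were above 0. At day 7 median and mean differed in sign for tubular injury (-0.062 and 0.026), p53 (0.034 and -0.0031), perirenal fat (0.029 and -0.013) and adrenal cortex (0.015 and -0.0044, test down). For the mean effect they did so for collecting duct (0.0096 and -0.0091), p53 (0.031 and -0.011), hypoxia (0.0053 and -0.040), red blood cell (0.014 and -0.015) and perirenal fat (0.054 and -0.018), and the FOXO list had both above 0 (0.019 and 0.0037) with the test down.

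The higher Mir182 row under anti-miR-182 was weighed with tests of which the cluster and inhibitor ones were chosen after the result was seen and the one on other microRNA genes before. A shift in the signal of all microRNA rows by as much as Mir182 is excluded. The other 362 had a median mean effect of 0.0531, with 0 as large as that of Mir182. Their median placebo level (4.5) was as low as that of Mir182 (4.51), so a rise in RNA to which these rows respond weakly is not excluded. The values argue against higher transcription of the whole cluster. The larger of the Mir96 and Mir183 effects was 0.122, and their upper 95% bounds were 0.136 and 0.287 against 1.45 for Mir182. Such transcription is not excluded, because the placebo levels of all 3 lie below the lower quartile of genes, where rows may respond weakly. Mir182 itself had such a low placebo level (4.51, against 4.67 for Mir96) and still differed by 1.45. Signal from the inhibitor or from its duplex with miR-182, which may keep the microRNA from decay or bind the probes, also stays open: it might fade with time, and the effect at day 7 minus day 2 was -0.553 ± 0.338 and did not pass in limma. A higher row on this array therefore does not tell whether miR-182 was active.

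Comparisons were also run with the arrays regrouped, a test written before the data were examined. Counts of splits include the real grouping. Within a day and with time there are 10 splits, too few for a share under 0.05. At day 2 and day 7 the real gene count was 0, which all 10 splits reach by construction (highest other 0 and 1), so nothing follows from it. For lists 5 gave at least the real 9 at day 2 (highest other 11) and 5 at least the real 10 at day 7 (highest other 19). With time they were 1 for genes in placebo (real 5080, highest other 0) and 6 for lists (real 11, highest other 15), and 1 (real 5002, highest other 0) and 3 (real 11, highest other 15) under anti-miR-182. Every other split with time mixes arrays of both days in each group. The day difference then enters the spread, which hides single genes, while part of it stays between the groups and can still shift lists. These counts with time therefore do not measure chance. For the mean effect 2 of 100 splits gave at least the real 1 gene (highest other 1). That share is under 0.05, but another grouping also gave 1 gene, so chance is less likely and not excluded for it. At least the real 9 lists came from 44 splits (highest other 16), so chance is not excluded for their number.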
